A study of Oryza sativa with 24 samples.

How the data were processed

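RNA from whole rice seedlings (root and shoot together) of 4 genotypes was hybridised to Agilent one-colour rice expression arrays, 1 array per sample. The genotypes were FL478, Hassawi, Nonabokra and IR29, each grown with 0 or 120 mM NaCl, with 3 replicates per group, which gave 8 groups and 24 arrays. Per the labels, seedlings in the salt groups had stress at reduced strength for 24 h from day 13, then 48 h at full strength, and were 16 days old when sampled. Per the file headers, the deposited scan values are Cy3 fluorescence intensity per spot, produced by Agilent Feature Extraction 10.7.3.1, which subtracted background and detrended each array but did no scaling between arrays. The deposited scans also hold 0 or 1 flags per spot, an indicator rather than an intensity, for saturation, outlying pixels and a signal well above background. A second deposited table, the series matrix, holds the same processed intensity for all samples, rounded. Its 3 columns for FL478 0 mM held the values of the 3 Hassawi 0 mM scans, while every other column was equal to its own scan, within the rounding, in 100% of spots, so the scans were used and the matrix served as an alternative only.

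Each array held 45151 spots, of which 43734 were not controls. Spots of one probe were averaged, which left 42477 probes. The processed signal was put on the log2 scale and each array's 75th percentile was subtracted. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which kept 34459 probes for 23696 loci, and 26515 probes were well above background on all 24 arrays. No minimum fold change was set. The 75th percentile of the signal ranged from 461.4 to 6203.9 between arrays, a ratio of 13.4, and between 69.6% and 87.1% of probes were well above background on an array. No spot was saturated. Between 15 and 119 spots per array were marked as outliers and were left out of the averages and of the 75th percentile. The number of arrays limits the precision: the median standard error of a log2 change was 0.4 within 1 genotype, 0.2 for the average over genotypes and 0.57 for a difference between genotypes.

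The comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on 8 group means, all 24 arrays together, one estimate of the spread per probe). All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 was the threshold. Values given after ± are standard errors of the fitted log2 change from limma (n = 3 arrays per group) unless marked SD, and the average over genotypes rests on 12 arrays per dose. These standard errors use the spread of a probe pooled over all 24 arrays, not that within 1 genotype. The comparisons were the salt effect in each genotype, its average over the 4 genotypes, its difference from IR29 in each of the other 3 genotypes, an F test of any such difference, and each genotype against IR29 without salt. IR29 was the reference because it is a common salt-sensitive check. These comparisons, the gene lists, the rule for naming genes and most of the alternatives were chosen before the data were examined. Same-numbered replicates were scanned on the same day and shared a slide within a pair of genotypes (FL478 with Hassawi, Nonabokra with IR29), according to the scan headers. After group means were removed, the 0 and 120 mM arrays of a genotype on the same slide correlated between -0.05 and 0.38, above 0.1 in 7 of 12 pairs, against -0.32 to 0.10 in 24 pairs with different replicate numbers, on different slides. Replicate and slide were therefore tried as blocks and were left out of the fit reported.

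The files identify genes by RAP locus and give no gene names or descriptions. Names were written by hand beside 217 loci. These pairs were then checked against a gene table of another rice assembly, which has names but no RAP loci, by chromosome and by the order of the loci along it. The table held 144 of the names, 134 of them on the chromosome stated in the locus identifier, and 133 passed both checks; 73 names had no entry. Of the 217 pairs, 77 were fixed before the data were examined and stayed in their lists whatever the check gave. The other 140 were written after the files were seen, because lists planned by description could not be filled, though before any gene's values were read, and only those that passed were kept. A locus whose name did not pass is given by its identifier with the words "entered as". Each gene was represented by its tested probe with the highest mean signal. NHX4 and NRT2.2 were not measured. Lists of glutathione S-transferases, class III peroxidases and cytosolic ribosomal proteins could not be formed without descriptions. Heat shock proteins kept 2 members, metallothioneins 1 and pathogenesis-related proteins 1, too few for a list test.

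The rule named the most changed genes with a description in each comparison, up to 4 members of each list with the smallest adjusted p in the average salt effect, and 9 salt markers whatever their p. Because the files hold no descriptions, loci ranked by change without a listed name are given as identifiers, at most 2 in each direction per comparison. For the salt effects and the differences without salt these were taken from loci with all arrays of one group above all arrays of the other, in at least 3 genotypes for the average. Where a group was not well above background on any array, no fold is given, and a log2 change of such a gene or locus rests on signals at the background, so its size is uncertain. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with a correlation estimated for each list and with fry, which tests the members against no change and not against other genes.

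The alternatives were quantile normalization, median centring, the series matrix values, normexp background correction with an offset of 50, array weights, trended and robust variance, probe filters, other ways to treat several probes per gene, a 2-fold minimum, a fit of only the genotypes compared, replicate and slide blocks, and each array left out in turn. Normexp was planned on the mean spot signal, which the scans do not hold, and was run on the median signal. Whole counts were also compared with other groupings of the arrays, up to 100 drawn with seed 20240607. The fit was tested on simulated data, made from each genotype's probe means with normal noise of the probe's residual spread, with salt changes of log2 1, 2, 3 or 4 added to 50 probes each of 34222: 44% of log2 changes of 2 were recovered in FL478, 42% in IR29 and 88% in the average over genotypes, with 9, 8 and 11 unchanged probes called. In a further simulated set a raised list was called by camera and 0 of 15 other lists were. Its noise was independent between genes, while the estimated correlation of the real lists reached 0.788. It therefore could not show false list calls that come from such correlation.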

Results

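Gene expression was measured in whole rice seedlings, root and shoot together, after 24 h at reduced strength and 48 h at full strength of 0 or 120 mM NaCl. The 4 genotypes were FL478 (a salt-tolerant inbred line bred from a cross of IR29 with the landrace Pokkali), Hassawi (a landrace from Saudi Arabia), Nonabokra (a salt-tolerant landrace, the source of the HKT1;5 allele that limits sodium in shoots) and IR29 (a salt-sensitive variety used as a check). Each genotype and dose had 3 arrays, 24 in all, and 34459 probes for 23696 loci were tested. The signal at the 75th percentile of an array ranged from 461.4 (IR29 120 mM replicate 3) to 6203.9 (Nonabokra 0 mM replicate 1), and the second brightest array was IR29 0 mM replicate 3 with 4709.4. Changes are log2 differences of intensity scaled to each array's 75th percentile, 120 mM minus 0 mM, with their standard errors.

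The arrays of a genotype were not all alike. Over 806 probes that separated the genotypes, the correlation between arrays of one genotype ran from 0.83 to 0.94 in Nonabokra and from 0.65 to 0.96 in IR29. There, replicate 3 at 0 mM reached only 0.65 to 0.70 with the other IR29 arrays. In FL478, replicate 1 at 120 mM had a correlation of 0.41 to 0.47 with the other FL478 arrays, which had 0.87 to 0.95 among themselves. The 6 Hassawi arrays had 0.32 to 0.69 among themselves, with a median of 0.53. No array had a correlation above 0.06 with an array of another genotype. Each probe's mean over all arrays was removed before these correlations, which by itself lowers those between genotypes.

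**Figure D1:**
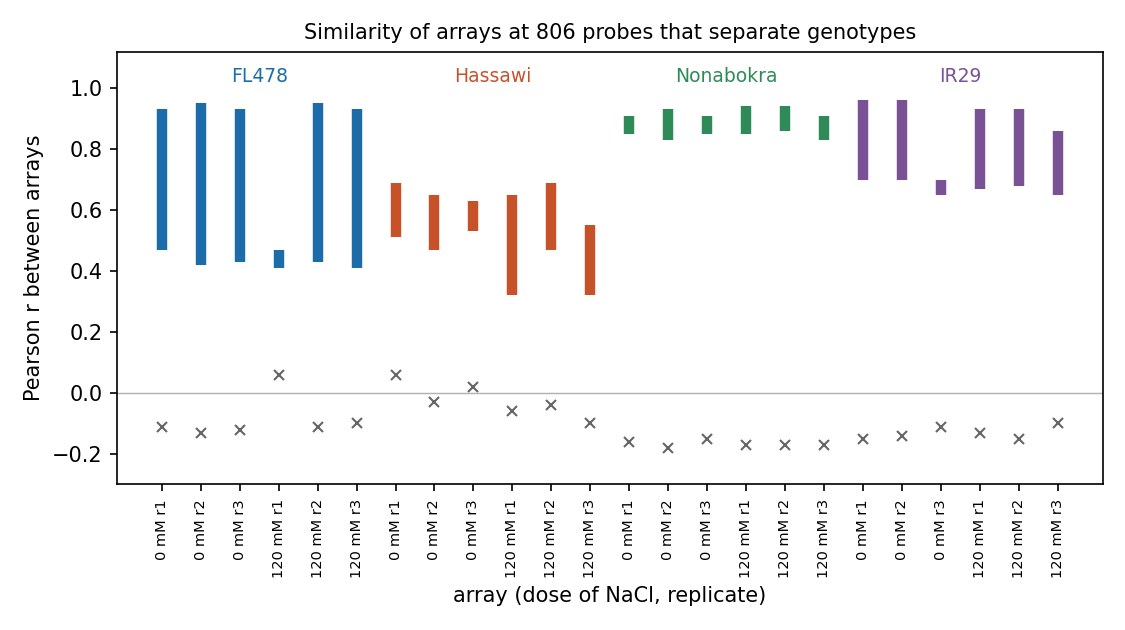
Similarity of the 24 arrays over 806 probes that separate the genotypes: each bar spans the lowest to the highest Pearson correlation of an array with the other arrays of its genotype, and each cross marks its highest correlation with an array of another genotype (no unit). The bars of FL478 120 mM replicate 1 (0.47) and of the Hassawi arrays (0.69 at most) end lowest. Next is the bar of IR29 0 mM replicate 3 (0.70), and no cross lies above 0.06. Each probe's mean over all arrays was removed first, which by itself lowers correlations between genotypes.

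The first comparison asked which genes answered salt in the average over the 4 genotypes. Genes for LEA proteins and dehydrins, hydrophilic proteins that accumulate in drying seeds and under water deficit, showed the largest rises among the lists. RAB16B rose by 7.41 ± 0.75 (170-fold, adjusted p = 1.4e-06), LEA3 by 7.20 ± 0.69 (147-fold, adjusted p = 6.4e-07) and the dehydrin gene RAB16A/RAB21 by 6.87 ± 0.66 (117-fold, adjusted p = 6.9e-07), each in the same direction in 12 of 12 same-slide pairs of arrays. Os02g0669100, entered as RAB25, a name that the gene table of the check held on another chromosome, rose by 2.02 ± 0.17 (adjusted p = 1.3e-07). All 8 measured members of this list rose, over all probes and when adjusted over the list alone, with a median of 5.2. The list ranked above other genes (camera adjusted p = 9.5e-10), with an adjusted p = 0.068 with an estimated correlation.

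Transcription factors of the stress response rose with them. HOX24, a homeodomain-leucine zipper gene, rose by 6.75 ± 0.48 (adjusted p = 1.9e-08), and by 3.72 with normexp background correction. In Nonabokra it was not above background on any of the 3 arrays without salt, and its change was 8.18, or 3.96 with normexp. HOX22, its close relative, rose by 3.28 ± 0.41 (adjusted p = 1.3e-05), NAC6, a NAC factor of stress tolerance, by 1.61 ± 0.14 (adjusted p = 2e-07) and DREB2A, which binds the dehydration-responsive element, by 1.01 ± 0.11 (adjusted p = 4.2e-06). Of 15 measured members 11 rose and 4 did not pass the test; adjusted over the list alone 11 rose and 1 fell (camera adjusted p = 1.8e-07, adjusted p = 0.068 with an estimated correlation).

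In the list of abscisic acid signalling, type 2C protein phosphatases, which hold the pathway back, led the changes. PP2C68 rose by 3.84 ± 0.27 (14.3-fold, adjusted p = 1.6e-08), PP2C51 by 3.98 ± 0.41 (adjusted p = 1.6e-06, and by 2.68 with normexp) and PP2C50 by 1.56 ± 0.15 (adjusted p = 1.1e-06). The transcription factor bZIP23, a positive regulator of the pathway, rose by 1.19 ± 0.13 (adjusted p = 2.5e-06). Of 14 members 10 rose, 11 when adjusted over the list alone, and none fell (camera adjusted p = 1.6e-08, adjusted p = 0.043 with an estimated correlation). Genes that make and break down the hormone went both ways, 2 of 6 up and 2 down over all probes and adjusted over the list alone (camera adjusted p = 0.87). Os07g0154100, entered as the synthesis gene NCED4, rose by 4.40 ± 0.51 (adjusted p = 6.3e-06), and by 1.53 with normexp. In IR29, where it was not above background without salt, its change was 5.85, or 2.5 with normexp. Among the 8'-hydroxylase genes of breakdown, ABA8ox2 rose by 1.25 ± 0.23 (adjusted p = 0.00059) and ABA8ox1 fell by 1.35 ± 0.30 (adjusted p = 0.0025). NCED3, another synthesis gene, had a change of 0.10 ± 0.26 (adjusted p = 0.81). Os12g0617400, entered as NCED5, fell by 0.80 ± 0.25 (adjusted p = 0.025), but not without Nonabokra 120 mM replicate 1 (adjusted p = 0.051) or with normexp background correction (adjusted p = 0.27).

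Genes of sodium and potassium transport moved in both directions. HKT1;4, a sodium transporter of leaf sheaths, fell by 2.59 ± 0.46 (adjusted p = 0.00044) with a dim signal, and by 0.39 with normexp background correction, where it did not pass (adjusted p = 0.4). AKT1, the main inward potassium channel of roots, fell by 1.02 ± 0.17 (2.02-fold, adjusted p = 2e-04). Os07g0666900, entered as the vacuolar antiporter NHX1, rose by 0.98 ± 0.25 (1.97-fold, adjusted p = 0.0079), and CIPK24, the kinase of the SOS pathway, by 0.45 ± 0.13 (adjusted p = 0.014), though with normexp its adjusted p was 0.07. HKT1;5, which takes sodium back from the xylem, had a change of -0.12 ± 0.49 (adjusted p = 0.89, 95% interval -1.14 to 0.90), HKT2;1, which takes up sodium in roots, of -0.45 ± 0.34 (adjusted p = 0.35), and Os12g0641100, entered as the plasma membrane antiporter SOS1, of 0.16 ± 0.09 (adjusted p = 0.2). Of 14 members 3 rose and 3 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.88).

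In osmolyte metabolism, P5CS1, which makes proline, rose by 0.96 ± 0.10 (1.95-fold, adjusted p = 2.4e-06) and RINO1, which starts inositol synthesis, by 1.46 ± 0.31 (adjusted p = 0.0021). TPP1, a trehalose-phosphate phosphatase, fell by 1.89 ± 0.25 (3.69-fold, adjusted p = 2.4e-05) and the betaine aldehyde dehydrogenase BADH2 fell by 0.37 ± 0.10 (adjusted p = 0.012). Of 7 members 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.91). The salt marker gene salT, which encodes a mannose-binding lectin, rose by 1.86 ± 0.30 (3.64-fold, adjusted p = 0.00019). Among 10 genes that scavenge reactive oxygen, 2 rose and 1 fell (camera adjusted p = 0.88), and the list's median was -0.11 while its mean was 0.03. The fall was that of APX3, an ascorbate peroxidase gene (adjusted p = 0.031), which did not pass in 13 of 32 alternatives, 11 of them refits without 1 array. CATB, a catalase gene, rose (adjusted p = 0.013), but not with normexp (adjusted p = 0.065). The cytosolic superoxide dismutase gene SODCC2 rose by 1.1 ± 0.18 (adjusted p = 0.00022).

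Genes of DNA replication and cell division were lower with salt. PCNA, the sliding clamp of DNA polymerase, fell by 1.17 ± 0.26 (2.25-fold, adjusted p = 0.003), and the mitotic genes CYCB2;2, CYCB2;1 and CDKB2 fell by 1.42 ± 0.37 (adjusted p = 0.0088), 1.17 ± 0.33 (adjusted p = 0.012) and 1.02 ± 0.28 (adjusted p = 0.011). Of 10 members 9 fell and 1 did not pass, with a median of -1.03 (camera adjusted p = 0.00016, adjusted p = 0.4 with an estimated correlation). Cellulose synthase genes were lower too: 6 of 9 fell, with a median of -0.72, among them CESA5, a primary wall gene, by 0.74 ± 0.14 (adjusted p = 0.00081) and CESA4, a secondary wall gene, which fell by 0.72 ± 0.19 (adjusted p = 0.0079) (camera adjusted p = 0.0044, adjusted p = 0.19 with an estimated correlation). Of 10 genes of cell wall expansion 4 fell and none rose. The expansin gene EXPA1 fell by 1.67 ± 0.30 (3.18-fold, adjusted p = 0.00046) and EXPB3 fell by 0.96 ± 0.24 (adjusted p = 0.0062). As a list they were near the threshold, with a camera adjusted p = 0.049 that ranged from 0.022 to 0.14 over the refits without 1 array. It also did not pass with an estimated correlation (adjusted p = 0.51), the mean of all probes of a gene (0.095), the replicate block (0.071), quantile normalization (0.065) or only members whose names passed the position check (0.054). It was above 0.05 in 12 of the 24 refits, those without replicate 3 of FL478 or Nonabokra or IR29 at either dose, without replicate 2 of Nonabokra or IR29 at 0 mM, and without Hassawi 0 mM replicates 2 or 3 or 120 mM replicates 1 or 3.

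Water channel and root genes included several lower members. Of 15 aquaporins 4 fell and none rose (camera adjusted p = 0.11, but 0.0094 with normexp). By fry, which asks whether members changed at all and not whether they rank apart from other genes, the adjusted p was 0.037. The tonoplast aquaporin TIP2;1 fell by 2.67 ± 0.57 (adjusted p = 0.0022), and the plasma membrane aquaporins PIP2;5 and PIP2;4 fell by 1.80 ± 0.54 (adjusted p = 0.019) and 1.64 ± 0.48 (adjusted p = 0.017). Of 9 root markers 5 fell, the same adjusted over the list alone. Their list had a camera adjusted p = 0.042, which ranged from 0.021 to 0.088 over the refits without 1 array. It did not pass with an estimated correlation (adjusted p = 0.19), with only the 5 members whose names passed the position check (0.17) or with the series matrix values (0.059). It was above 0.05 in 8 of these refits, those without replicate 3 of any group but Hassawi 120 mM, and without Hassawi 120 mM replicate 2. NRT2.1, a high-affinity nitrate transporter, fell by 2.29 ± 0.51 (adjusted p = 0.0029), but not with the series matrix values (adjusted p = 0.084) or with normexp (adjusted p = 0.23). NRAMP5, a manganese transporter of roots, fell by 0.96 ± 0.26 (adjusted p = 0.0098). The 4 photosynthesis genes, markers of the shoot, held 1 that fell, PSAH of photosystem I, by 0.60 ± 0.18 (adjusted p = 0.019), and their list did not pass (camera adjusted p = 0.91).

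Other lists did not pass as lists. In jasmonate synthesis and signalling 1 of 10 rose and 3 fell (camera adjusted p = 0.11, but 0.025 with normexp and 0.022 without IR29 120 mM replicate 2). The repressor gene TIFY11C rose by 1.90 ± 0.30 (3.74-fold, adjusted p = 0.00013), while AOS1, an allene oxide synthase of jasmonate synthesis, fell by 1.00 ± 0.20 (adjusted p = 0.001). None of 6 measured genes of nitrogen uptake and assimilation passed (camera adjusted p = 0.87), and glutamine synthetase GS2 had a change of -0.46 ± 0.32 (adjusted p = 0.32). Of the 3 reference genes ACT1, an actin gene, fell by 0.67 ± 0.17 (adjusted p = 0.008). Os01g0328400, entered as UBQ5, a name that the gene table of the check held on another chromosome, fell by 0.49 ± 0.15 (adjusted p = 0.019). Os03g0177500, entered as EF1A, had a change of 0.10 ± 0.17 (adjusted p = 0.71). The reference list had a camera adjusted p = 0.24. Of the loci without a name in the files, Os11g0181200 (7.87 ± 0.74) and Os06g0324400 (7.21 ± 0.88) rose most, and Os12g0227500 (-5.03 ± 0.35) and Os04g0310100 (-4.71 ± 0.52) fell most.

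Over all probes, 9213 changed in the average over genotypes (26.74% of those tested, limma), 4367 higher and 4846 lower, and 2892 of them changed at least 2-fold, 1513 higher and 1379 lower. At an unadjusted p under 0.05 the number was 12981. The count was 5674 with normexp, 3047 higher and 2627 lower, and 16350 with array weights.

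**Figure D2:**
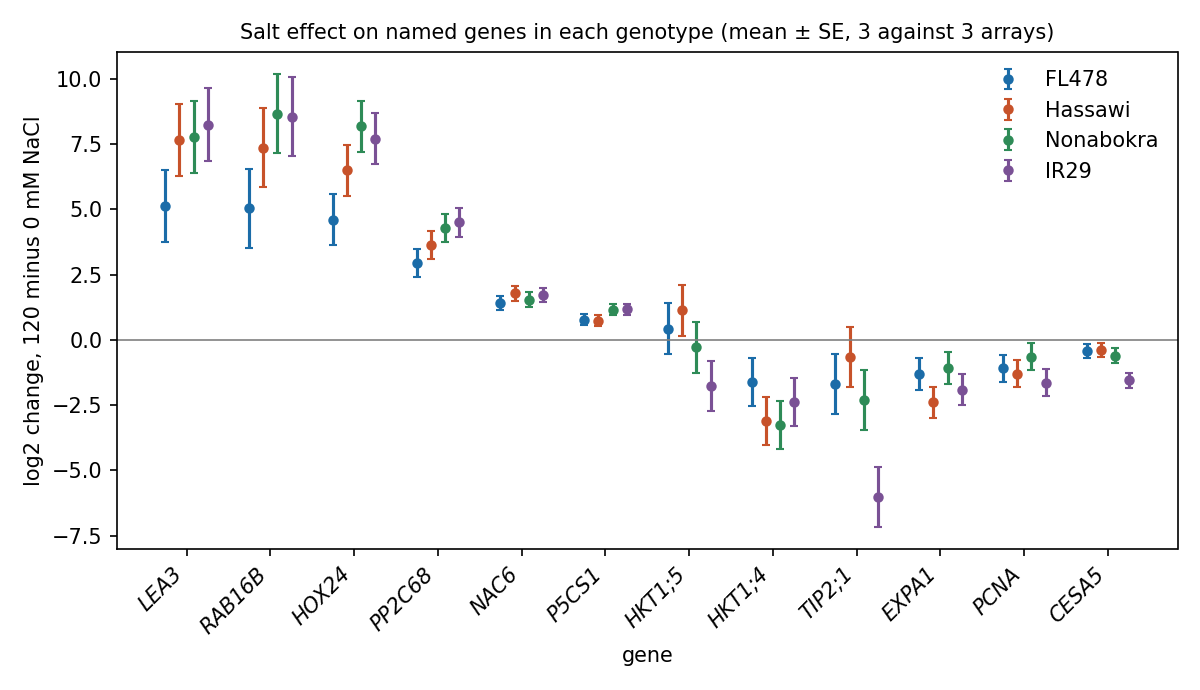
Salt effect on 12 genes in each of 4 genotypes: points are fitted log2 changes of intensity (120 mM minus 0 mM NaCl) and bars their standard errors, n = 3 arrays per group. LEA3 lies between 5.12 and 8.25 in all 4 genotypes, and TIP2;1 between -6.01 in IR29 and -0.67 in Hassawi.

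In FL478, PP2C68 rose by 2.96 ± 0.54 (adjusted p = 0.011), HOX24 by 4.61 ± 0.97 (adjusted p = 0.028) and NAC6 by 1.41 ± 0.28 (adjusted p = 0.018), each in 3 of 3 same-slide pairs. LEA3 had a change of 5.12 ± 1.38 (adjusted p = 0.12), with 0 mM arrays that varied widely (SD 3.77, n = 3). None of the 8 LEA and dehydrin genes passed over all probes and 4 rose when adjusted over the list alone, with a list median of 2.01 (camera adjusted p = 1.3e-06, adjusted p = 0.18 with an estimated correlation, and 0.086 by fry). Of 15 stress transcription factors 2 rose, 9 adjusted over the list alone (camera adjusted p = 6.3e-09, adjusted p = 0.06 with an estimated correlation), and of 14 genes of abscisic acid signalling 1 rose, 3 adjusted over the list alone (camera adjusted p = 1.3e-06, adjusted p = 0.06 with an estimated correlation). DNA replication genes ranked low as a list (camera adjusted p = 0.00039, adjusted p = 0.46 with an estimated correlation, and 0.21 by fry) and did not without FL478 120 mM replicate 3 (adjusted p = 0.06), with none of 10 past the test. Among loci without a name, Os10g0378500 rose by 6.49 ± 0.74 and Os06g0216300 by 6.36 ± 1.30, and Os05g0212900 fell by 7.66 ± 1.28 and Os10g0167900 fell by 6.66 ± 1.31.

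In FL478 244 probes changed, 221 higher and 23 lower, and 3201 had an unadjusted p under 0.05. The count was 102 without 120 mM replicate 1, the array that stood apart, 139 without 0 mM replicate 1, 136 without 0 mM replicate 2 and 137 without 120 mM replicate 3. Without replicate 1 at 120 mM, PP2C68 (adjusted p = 0.083), HOX24 (adjusted p = 0.14) and NAC6 (adjusted p = 0.12) no longer passed. PP2C68 also did not pass without 0 mM replicates 1 (0.051) or 2 (0.067) or 120 mM replicate 3 (0.062). Of the 6 refits without 1 FL478 array, HOX24 passed only in that without 0 mM replicate 1 (adjusted p = 0.057 to 0.16 in the others), and NAC6 only in that without 120 mM replicate 2 (adjusted p = 0.052 to 0.12 in the others). With normexp neither passed, HOX24 at 2.72 (adjusted p = 0.19) and NAC6 at 1.39 (adjusted p = 0.064).

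In Hassawi, LEA3 rose by 7.65 ± 1.38 (adjusted p = 0.0039), RAB16A/RAB21 by 6.98 ± 1.32 (adjusted p = 0.0058), HOX24 by 6.49 ± 0.97 (adjusted p = 0.00076), PP2C68 by 3.63 ± 0.54 (adjusted p = 0.00076) and NAC6 by 1.78 ± 0.28 (adjusted p = 0.0012). Of 8 LEA and dehydrin genes 5 rose, 8 adjusted over the list alone (camera adjusted p = 6.6e-10, adjusted p = 0.077 with an estimated correlation). Of 14 abscisic acid signalling genes 4 rose, 6 adjusted over the list alone (camera adjusted p = 7.8e-07, adjusted p = 0.077 with an estimated correlation), and of 15 stress transcription factors 4 rose, 9 adjusted over the list alone (camera adjusted p = 5.1e-07, adjusted p = 0.077 with an estimated correlation). DNA replication genes ranked low as a list, with none past the test (camera adjusted p = 0.002, adjusted p = 0.66 with an estimated correlation, and 0.27 by fry). Of the loci without a name, Os04g0460900 and Os04g0613300 were above background on 3 of 3 arrays with salt and on 0 without, and Os11g0233400 and Os09g0309900 on 3 without and 0 with salt. The sizes of these differences (11.46, 7.64, -9.28 and -8.21) therefore rest on the background. The first pair lies from Os04g0431300 to Os04g0674600, a stretch of chromosome 4 where Hassawi differed from IR29 at 28 probes, and a difference in alleles between the seedlings of the doses was not excluded, there or elsewhere in Hassawi. Outside chromosome 4, 5.16% of 504 probes that mark the genotypes changed at least 8-fold in Hassawi, against 0.54% of 1286 in the other genotypes, so part of the Hassawi changes given here need not be an effect of salt. In Hassawi 1070 probes changed, 665 higher and 405 lower (5345 at an unadjusted p under 0.05). The count was 621 without 0 mM replicate 3 and 612 without 120 mM replicate 2. It was 721 without FL478 120 mM replicate 1 and Hassawi 120 mM replicate 3, the arrays that stood most apart within their genotypes at 120 mM.

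In Nonabokra, RAB16B rose by 8.67 ± 1.51 (adjusted p = 0.0028), RAB16A/RAB21 by 8.65 ± 1.32 (adjusted p = 0.00096), LEA3 by 7.78 ± 1.38 (adjusted p = 0.0032), PP2C51 by 4.87 ± 0.82 (adjusted p = 0.0022) and PP2C68 by 4.28 ± 0.54 (adjusted p = 0.00018). P5CS1 rose by 1.15 ± 0.21 (adjusted p = 0.0033), but did not pass with normexp (0.99, adjusted p = 0.077). Of 8 LEA and dehydrin genes 6 rose, 8 adjusted over the list alone (camera adjusted p = 2e-12, adjusted p = 0.038 with an estimated correlation). Of 14 abscisic acid signalling genes 6 rose, 7 adjusted over the list alone (camera adjusted p = 6e-11, adjusted p = 0.015 with an estimated correlation), and of 15 stress transcription factors 5 rose, 8 adjusted over the list alone (camera adjusted p = 1.9e-07, adjusted p = 0.069 with an estimated correlation). Cellulose synthase genes ranked low as a list, with none past the test alone (camera adjusted p = 0.0044, adjusted p = 0.18 with an estimated correlation). Root markers ranked low too, with a median of -0.86 (camera adjusted p = 0.024, adjusted p = 0.17 with an estimated correlation). They did not pass with only the members whose names passed the position check. DNA replication genes had a median of -0.27 and did not pass as a list (camera adjusted p = 0.4, and 0.011 without 0 mM replicate 3). Among loci without a name, Os11g0181200 rose by 9.57 ± 1.47 and Os11g0451700 by 8.99 ± 1.90, and Os10g0515900 fell by 5.06 ± 1.25 and Os10g0508700 fell by 4.16 ± 1.05. In Nonabokra 1014 probes changed, 804 higher and 210 lower (5199 at an unadjusted p under 0.05). The count was 544 without 0 mM replicate 1, the brightest array, 663 without 0 mM replicate 3, 467 without 120 mM replicate 1 and 414 without 120 mM replicate 2.

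In IR29, RAB16B rose by 8.55 ± 1.51 (adjusted p = 0.0015), LEA3 by 8.25 ± 1.38 (adjusted p = 0.00099), PP2C68 by 4.50 ± 0.54 (adjusted p = 6.5e-05), salT by 2.69 ± 0.60 (adjusted p = 0.0079) and SODCC2 by 1.94 ± 0.36 (adjusted p = 0.0023). TIP2;1 fell by 6.01 ± 1.15 (adjusted p = 0.0026), TPP1 fell by 2.58 ± 0.50 (adjusted p = 0.0028) and CESA5 fell by 1.55 ± 0.28 (adjusted p = 0.0018). Of 8 LEA and dehydrin genes 7 rose, 8 adjusted over the list alone (camera adjusted p = 3.3e-09, adjusted p = 0.10 with an estimated correlation). Of 15 stress transcription factors 9 rose, also 9 adjusted over the list alone (camera adjusted p = 8.5e-06, adjusted p = 0.14 with an estimated correlation), and of 14 abscisic acid signalling genes 6 rose, 7 adjusted over the list alone (camera adjusted p = 7.2e-07, adjusted p = 0.097 with an estimated correlation). Of 10 DNA replication and cell division genes 3 fell, with a median of -1.81 (camera adjusted p = 8.5e-06, adjusted p = 0.27 with an estimated correlation). In these whole seedlings the root markers ranked low too, with a median of -0.95 (camera adjusted p = 0.018, adjusted p = 0.14 with an estimated correlation). They did not pass with only the members whose names passed the position check. The photosynthesis genes did not pass as a list (camera adjusted p = 0.59). Among loci without a name, Os11g0181200 rose by 9.96 ± 1.47 and Os09g0127700 by 9.40 ± 1.51, and Os10g0452900 fell by 8.50 ± 1.03 and Os11g0566800 fell by 6.44 ± 0.77. In IR29 3442 probes changed, 1847 higher and 1595 lower (8635 at an unadjusted p under 0.05). The count was 1936 without 0 mM replicate 1, 2000 without 0 mM replicate 2 and 1885 without 120 mM replicate 3. With normexp background correction, under which the median change of all probes in IR29 was 0.33 instead of 0.02, 70.7% of the changed probes were higher, against 53.7%.

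**Figure D3:**
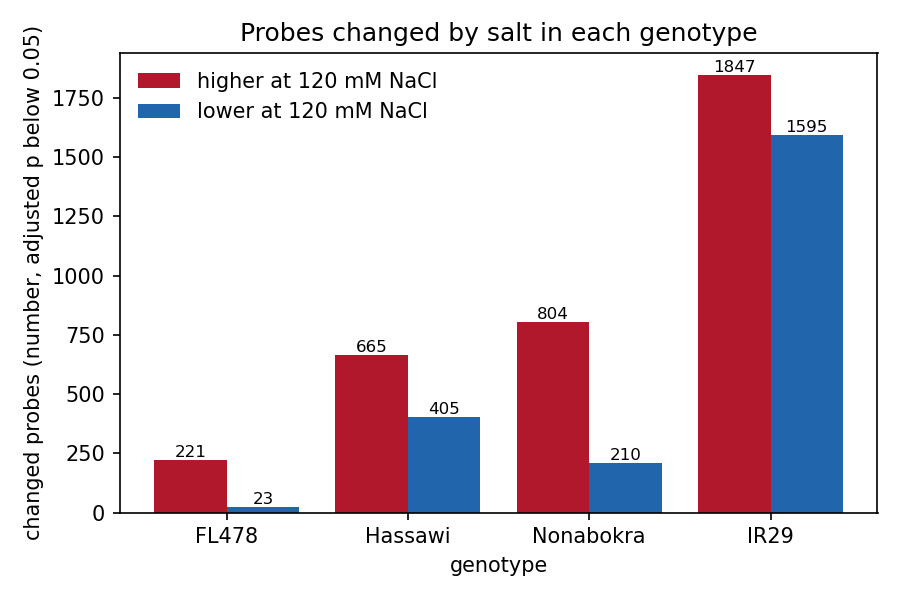
Number of probes (of 34459 tested) that changed with salt at an adjusted p under 0.05 in each genotype, with bars for probes higher and lower at 120 mM NaCl, n = 3 arrays per group. The bars run from 221 higher and 23 lower in FL478 to 1847 higher and 1595 lower in IR29.

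The changes were shared between genotypes in part. LEA3, RAB16B and PP2C68 had positive changes in all 4 genotypes, and 175 probes were called higher in all 4, against 0.01 if the calls were independent, with 6 called lower in all 4. Of the 221 probes higher in FL478, 202 were also higher in Hassawi (4.3 if independent), and of the 804 higher in Nonabokra, 664 were higher in IR29 (43.1 if independent). Because the tests of the 4 genotypes share 1 estimate of spread per probe, their calls are not independent even without a shared response. The numbers expected under independence are therefore only a rough guide. Opposite calls numbered 0 to 3 per pair of genotypes and direction. Across probes, which are not independent replicates, the log2 changes of a pair of genotypes had a Pearson correlation from 0.49 (Hassawi and IR29) to 0.68 (Nonabokra and IR29) and a Spearman correlation from 0.46 to 0.64. In all, 1044 probes were called the same way in at least 2 genotypes, while 1347 were called higher and 1678 lower in only 1. A call in only 1 genotype does not show a response particular to it. Of all probes called in a genotype, 90.1% to 99.2% changed in the same direction in each other genotype. These shares include probes called in several genotypes.

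Differences between genotypes in the salt effect were tested against IR29, the salt-sensitive check. No listed gene differed among the genotypes by the F test, LEA3 (adjusted p = 1) and the sodium transporter HKT1;5 (adjusted p = 1) included. The F test could miss such differences. Where simulated probes were changed in Hassawi alone, it recovered 4% of log2 changes of 1 and 44% of those of 2. A gene that did not pass is therefore not shown to respond alike in the genotypes. A pair of loci without a name, Os06g0272700 and Os11g0586800, rose in the other 3 genotypes and not in IR29. Os06g0272700 changed by 4.30 ± 0.45 in FL478, 4.31 ± 0.45 in Hassawi and 5.20 ± 0.45 in Nonabokra, against -1.28 ± 0.45 in IR29 (F test adjusted p = 4.6e-05). Its mean log2 level without salt was -2.81 in IR29 (SD 0.07, n = 3), above background on all arrays, and between -8.69 and -7.32 in the other genotypes, where at most 1 of 3 arrays was above background; with salt it was -4.10 in IR29 and between -3.64 and -3.0 in the others. Os11g0586800 changed by 4.44, 4.59, 4.87 and -1.36, each ± 0.48 (F test adjusted p = 0.00012). Os03g0734000 rose by 3.50 ± 0.45 in IR29 (adjusted p = 1e-04), a difference of -4.18 ± 0.64 in FL478 (adjusted p = 0.038) and of -3.98 ± 0.64 in Nonabokra (adjusted p = 0.03). With normexp background correction no probe was called higher than in IR29 in any of the 3 genotypes, so the differences of the first pair did not pass there. These 3 loci were named after their values were seen.

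Between FL478 and IR29 these were the 3 probes that differed (2 higher, 1 lower, limma), with 1770 at an unadjusted p under 0.05. With normexp 1 differed, which was lower. For Hassawi 50 probes differed from IR29, 17 higher and 33 lower (2041 unadjusted). With normexp 8 differed, all lower, and with quantile normalization 62, of which 30 were higher. Of the 50, 30 lay on chromosome 4, which held 8.8% of the tested probes. The Hassawi count was 25 without IR29 0 mM replicate 2 or 120 mM replicate 2, 26 without IR29 0 mM replicate 1, 27 without IR29 120 mM replicate 1 and 30 without IR29 0 mM replicate 3. Without FL478 120 mM replicate 1 and Hassawi 120 mM replicate 3 it was 87. For Nonabokra 8 probes differed, 4 in each direction (1144 unadjusted), and with normexp 1, which was lower. That count was 5 without any 1 of the 3 Nonabokra arrays at 120 mM, without Nonabokra 0 mM replicate 1 or without IR29 0 mM replicate 1, 4 without IR29 0 mM replicate 2 and 3 without IR29 120 mM replicate 2. By the F test 42 probes differed among the genotypes (1211 unadjusted), and 27 without IR29 0 mM replicate 2. By chance alone a share of 0.05 of the 34459 tested probes would have an unadjusted p under 0.05. The unadjusted numbers for Nonabokra and the F test lay below that share, that for FL478 near it and that for Hassawi above it. They are therefore little or no sign of further differences.

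Without salt, each genotype was compared with IR29. NRT2.1, the nitrate transporter, was higher in FL478 by 5.07 ± 1.02 (adjusted p = 0.0061) and in Nonabokra by 5.18 ± 1.02 (adjusted p = 0.0031), with 1 of 3 IR29 arrays above background. BADH1, a betaine aldehyde dehydrogenase gene, was higher than in IR29 in FL478 (0.82 ± 0.22, adjusted p = 0.045), Hassawi (0.85 ± 0.22, adjusted p = 0.031) and Nonabokra (1.04 ± 0.22, adjusted p = 0.0049). In Nonabokra CESA5 was higher by 1.06 ± 0.28 (adjusted p = 0.03). BADH1 was named after its values were seen. Probes were designed on a reference genome, so a difference between genotypes can also be a difference in sequence. FL478 and Hassawi shared slides that held no IR29 array, so their differences from IR29 without salt cannot be separated from a difference between slides. FL478 differed from IR29 at 1041 probes (595 higher, 446 lower), Hassawi at 1257 (686 higher, 571 lower) and Nonabokra at 1836 (923 higher, 913 lower). The largest differences were in loci without a name. In FL478 Os10g0192000 differed by 11.89 ± 1.37 and Os04g0142400 by -10.72 ± 2.21, in Hassawi Os09g0372100 differed by 10.26 ± 2.21 and Os07g0137600 by -11.04 ± 0.73, and in Nonabokra Os04g0424900 differed by 10.79 ± 1.83 and Os03g0846400 by -10.44 ± 1.05.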

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

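The tests of placement along the chromosomes, of alleles outside chromosome 4 and of response sizes, and the comparisons with other groupings of the arrays, were chosen after the results they concern were seen; the other tests were chosen before theirs, that of spot positions last of all but before any position was read.

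The results given here were singled out because the salt effect of 1 genotype differed from that of IR29 by a test of the difference itself. The numbers of such probes were 3 for FL478, 50 for Hassawi and 8 for Nonabokra, and 42 by the F test. In FL478 the differences from IR29 were 5.80 for Os11g0586800, 5.58 for Os06g0272700 and -4.18 for Os03g0734000. In Nonabokra they were 6.49 for Os06g0272700, 7.78 for Os11g0566800, -5.71 for Os04g0146800 and -4.99 for Os04g0210600. In Hassawi they were 13.14 for Os04g0460900, 6.42 for Os10g0569500, -8.31 for Os04g0599400 and -8.09 for Os11g0479300.

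The first pattern is that 30 of the 50 probes that differed between Hassawi and IR29 lay on chromosome 4 (60% against 8.8% of tested probes), 28 of them from Os04g0431300 to Os04g0674600. Chance placement along the chromosomes is argued against by Fisher's exact test (p = 1.7e-19), and a defect in one patch of the array surface by the spots of the 28 probes, since 97.4% of 1000 random sets of probes lay as close together or closer. Any other local defect of the array or its normalization stays open, since 0 other genotypes had an excess of changed markers in the segment but these had only 1 to 6 changed markers each. Different alleles in the Hassawi seedlings at 0 and 120 mM are a candidate explanation: outside chromosome 4, 26 of 504 probes that mark the genotypes changed at least 8-fold in Hassawi, against 7 of 1286 in the other genotypes together (Fisher's exact p = 1.6e-09). The 1286 add up marker sets drawn from the same probes, so members can recur and this p-value is only a rough guide. The Hassawi arrays also correlated at only 0.32 to 0.69 among themselves, and such variation can add changes of this size. The same test inside the segment (4 of 15 markers against 26 of 547, Fisher's exact p = 0.006) decides nothing, because 3 of the 4 are among the probes that drew the segment, and a salt response of Hassawi itself was not tested apart from this and stays open.

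The second pattern is that 244 probes changed in FL478, fewer than in any other genotype. Exchanged or unsalted arrays are argued against by salt scores taken from probes that changed in the other genotypes, since the lowest FL478 score at 120 mM lay 1.82 above the highest at 0 mM. In replicate 1 at 120 mM, 75% of only 4 markers were nearest to FL478 (in Hassawi 120 mM replicate 3, 54.5% of 11 to Hassawi). Its correlation with the other FL478 arrays was 0.41 to 0.47, so it may hold seedlings of a different line. Its correlation with any other genotype was at most 0.06, which decides nothing, because removing probe means lowers such values on every array. With larger marker sets it was not alone in a low share (66.7% to 80%, against 68.2% to 84% in IR29 0 mM replicate 3 and 63.7% to 87.7% in the Hassawi 0 mM arrays). Whether replicate 1 at 120 mM caused the low count is not decided by the refit without it. There the count was 102, against 919 or more in the other genotypes, but fewer arrays can also lower a count. All 6 refits without 1 FL478 array gave lower counts than 244, from 102 to 214. The spread of a probe is also pooled over the arrays of all genotypes, so spread added by this array enters the tests of each genotype. A smaller response in FL478 stays open. Response size was a genotype's change within a slide relative to the mean change of the other 3 genotypes, over probes called there. In FL478 it was 0.68 (SD 0.12, n = 3), and differed from the 9 other values with an exact permutation p = 0.023 (adjusted p = 0.092 over the 4 genotypes, smallest possible p 0.0045). Each genotype had its own reference, so the values are not exchangeable as the permutation assumes, and this p-value decides nothing.

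The third pattern is that 3442 probes changed in IR29, more than in any other genotype, although with array weights Nonabokra came first (13817, against 11108 in IR29). The very bright array IR29 0 mM replicate 3 is argued against as the source, since without it the count was 2949 and the highest of the others 1186. A larger response in IR29 stays open: its response size was 1.03 (SD 0.09, n = 3), with an exact permutation p = 0.059 against the 9 other values (adjusted p = 0.12, smallest possible p 0.0045). The limit of the permutation given for FL478 holds here too. IR29 and Nonabokra shared slides that held neither FL478 nor Hassawi, so a difference between the sets of slides cannot be separated from genotype in these values.

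Other groupings of the 24 arrays were fitted in the same way. Shuffling the dose within each genotype gave at most 24 changed probes in the average over genotypes, and 1 of 100 groupings, the real one, gave 9213, which excludes chance. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05; in each comparison 1 split, the real one, gave the highest count. The real count and the highest of the other splits were 244 and 1 in FL478, 1070 and 114 in Hassawi, 1014 and 0 in Nonabokra, 3442 and 2 in IR29. Without salt they were 1041 and 97 for FL478 against IR29, 1257 and 12 for Hassawi, and 1836 and 1645 for Nonabokra. The last of these splits set Nonabokra 0 mM replicates 1 and 3 and IR29 0 mM replicate 3 against the rest. Both very bright arrays were then on one side, and so were the arrays of replicate 3, which shared a slide. This points to a structure of the samples that was not tested.

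For the differences in salt effect the dose labels were shuffled first. As many probes as in the real grouping were called in 7 of 100 groupings for FL478 (highest other 1479), 7 for Hassawi (4972), 14 for Nonabokra (5692) and 10 for the F test (3449). Shuffled doses turn the salt effect itself into a difference between genotypes, which is why the genotype labels were then shuffled within each dose after genotype means were removed. That gave 3 of 100 groupings for FL478 (highest other 218), 1 for Hassawi (2), 13 for Nonabokra (1111) and 2 for the F test (45). The second way thus argues against chance for Hassawi and the F test, and the first does not. For the 3 probes of FL478 the share was under 0.05 by the second way only. Another shuffle gave 218 there, so chance stays open. For the 8 probes of Nonabokra neither way argues against it. These shares were not adjusted over the comparisons, and the shuffles did not keep arrays of a slide together. The high counts with shuffled doses follow from their construction, and those with shuffled genotypes (218 and 1111 probes) point to a structure of the samples, which was not tested.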

How the results depend on the processing

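Normexp on the median signal, the fits without the 2 brightest arrays, without the 2 arrays that stood apart or without the chromosome 4 segment, and the list tests on checked members alone, were chosen after seeing the data; the other alternatives were planned. Normexp on the mean signal was not run because the scans lack it.

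No named gene or list that was called changed direction in the alternatives where single genes or lists were read. Only counts were read with array weights, the probe filters, 1 probe per gene and fits of the arrays compared alone. The same holds for the fits without the brightest arrays, the arrays that stood apart or the chromosome 4 segment. Directions of other called probes were not compared. Of the named genes' values over comparisons and alternatives, 5762 kept their side of the threshold, 164 lost a call and 58 gained one; for lists 1383 kept it, 77 lost a call and 23 gained one. For counts, 301 stayed within 1.5 times and 79 did not. Pairing raised every salt count, from 244 to 293 in FL478, 1070 to 1455 in Hassawi, 1014 to 1429 in Nonabokra, 3442 to 4755 in IR29 and 9213 to 10810 in the average with the replicate number as a block, and to 310, 1439, 1336, 4553 and 10615 with the slide. The replicate block also added calls of named genes, such as PP2C51 in FL478 (adjusted p = 0.0041), HKT1;4 in Hassawi (0.023) and Nonabokra (0.017) and Os07g0666900, entered as NHX1, in Nonabokra (0.0075), and ended that of cell wall expansion in the average (0.071). Quantile normalization and median centring kept every count within 1.5 times, though with quantile normalization 48.4% of the probes that differed between Hassawi and IR29 were higher, against 34%, and with normexp 0%. Normexp on the median signal changed the background method and the signal together, and the cause was not tested; the counts were 123 in FL478, 446 in Hassawi, 515 in Nonabokra, 1965 in IR29 and 5674 in the average, 1, 8 and 1 for the differences of FL478, Hassawi and Nonabokra from IR29 in salt effect, 433, 465 and 757 for those without salt, 8 for the F test and 505 for probes shared by at least 2 genotypes. With normexp the median change of all probes was 0.33 in IR29 and -0.08 to 0.06 in the others, against 0.02 and -0.05 to 0. Signal over background limits how well a change is sized in genes not above background at 1 dose: that of HOX24 in Nonabokra was 8.18, and 3.96 with normexp. Among probes well above background on all 24 arrays, a filter that by construction removes genes silent in 1 genotype or dose, the differences in salt effect numbered 0, 8 and 0, those without salt 332, 415 and 617, and the F test gave 8.

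With limma array weights (0.22 to 8.76, highest in IR29 0 mM replicate 2) the counts were 928, 2340, 13817 and 11108 in the 4 genotypes in the order above and 16350 in the average, 226, 229 and 2718 for the differences in salt effect, 6283, 3309 and 17005 without salt and 1960 by the F test; the cause was not tested. The series matrix values gave 1631 in FL478 (62.6% higher, against 90.6%), 502 for its difference from IR29 and 395 by the F test, since its FL478 0 mM columns hold Hassawi values. With 1 probe per gene, which tests fewer probes, Nonabokra had 663 and IR29 2251. A 2-fold minimum left 2892 in the average. Fits of the arrays compared alone, with fewer arrays for the spread, gave 4, 117, 267 and 1152 in the 4 genotypes, and 0 for FL478 and 2 for Nonabokra in their differences from IR29. With an estimated correlation 1 list was called in the average, against 7. Without the 2 brightest arrays Nonabokra had 613, and the differences from IR29 were 33 for Hassawi and 3 for Nonabokra. Without the 2 arrays that stood apart FL478 had 85, the Hassawi difference 87 and the F test 80. Without the chromosome 4 segment the Hassawi difference had 7 and the F test 20.

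Leaving out each array in turn, with the remaining pair of a group assumed to vary like the others, gave 102 to 214 in FL478, 612 to 1014 in Hassawi, 414 to 1362 in Nonabokra, 1885 to 2949 in IR29 and 7805 to 9526 in the average. The differences from IR29 ran from 2 to 4 in FL478, 25 to 70 in Hassawi and 3 to 7 in Nonabokra, those without salt from 711 to 1006, 898 to 1230 and 1247 to 2082, and the F test from 27 to 60. Called lists numbered 5 to 8 and called named genes 54 to 55.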

Other observations

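The larger marker sets, used to place each array among the genotypes, were chosen after the result of the first set was seen.

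Heat shock proteins kept 2 of 15 written members, metallothioneins 1 of 6 and pathogenesis-related proteins 1 of 6, so nothing is said of these lists. In the average over genotypes Os09g0482600, an HSP90 gene whose product is a molecular chaperone, rose by 2.97 ± 0.62 (adjusted p = 0.0018), and HSP101, which frees aggregated proteins, rose by 1.59 (adjusted p = 0.00038). The metallothionein gene MT1 rose by 0.60 (adjusted p = 0.028), and PBZ1, a pathogenesis-related gene, had a change of -0.38 (adjusted p = 0.65). These genes were named after their values were seen.

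Of the 244 probes called in FL478, 97.1% to 99.2% had the same direction of change in each other genotype. With larger marker sets (72 to 106 probes), 66.7% to 80% of markers on FL478 120 mM replicate 1 were nearest to FL478, against 96.8% to 99.1% on replicates 2 and 3. The share nearest to their own genotype was also low in Hassawi 120 mM replicate 3 (74.7% to 81.9%), in Hassawi 0 mM replicates 1 (72.5% to 81.3%), 2 (81.3% to 87.7%) and 3 (63.7% to 77%), and in IR29 0 mM replicates 1 (81.8% to 97.1%), 2 (84.1% to 97.1%) and 3 (68.2% to 84%). In the 15 markers of the chromosome 4 segment, the Hassawi arrays without salt had a median distance of 0.60 to 0.77 from FL478 and 2.18 to 2.72 from IR29. Those with salt had 2.89 to 3.31 from FL478 and 0.77 to 1.47 from IR29. Of these markers 3 are among the probes that drew the segment. The distances were not tested as evidence of different alleles apart from a salt response of Hassawi.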
